A study of Bos taurus with 10 samples.

How the data were processed

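Mammary biopsies from both sides of the udder of 5 cows were hybridised to a printed bovine oligonucleotide array with 23232 features. Per the labels' protocols, 20 µg of each RNA was converted into aminoallyl cDNA with oligo-dT primers and coupled to Cy3 or Cy5, and the sides of a cow were hybridised together on 2 arrays with exchanged dyes. The labels give the dye of each side, from which every ratio was turned to once daily milking (ODM) over 2 milkings per day (TDM).

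Per the file headers, the arrays were read with Agilent Feature Extraction 9.1.3.1. The deposited scanner files hold mean and median pixel intensity and local background per channel on a linear scale, not normalized. They also hold a log10 ratio of red over green that, per the file headers, the software made after subtracting a fitted background surface and a LOWESS dye normalization. The table deposited by the authors for the whole series holds log2 values. Each column set against its array equalled the mean log2 of the median red and green intensity (r = 1), and so gives average brightness with no centring and no direction. Column medians ran from 7.04 to 8.07, in order of cows 7849, 3049, 01, 25 and 11, Cy5 then Cy3 array, 7.66, 7.04, 7.15, 7.32, 8.07, 7.19, 7.80, 7.20, 8.02 and 7.11. It has 23177 rows, of which 21539 were matched to a probe with 1 feature. How the authors chose the values left blank is not given in the sources used here. It holds no ratios, so the comparison could not be repeated on it. The flag columns of the scanner files (outlier, saturated, well above background) are other values, 0 or 1, as deposited.

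Ratios were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on mean intensity and median background, and arrays were normalized by loess with control, empty and outlier-flagged features at weight 0. Control features (1483, of which 960 were empty positions) and outlier-flagged features were left out, saturated ones kept. Features of a probe were averaged, the 2 arrays of a cow were averaged, and the 5 cow values were fitted against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. An exact sign-flip permutation test served the detected features. A total of 2 probes were saturated on all arrays in the channel of one side, and neither is named.

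The design, the alternatives and the rule for named items were fixed before the data were examined. Probes needed values in at least 3 cows, a minimum chosen after the data were seen, which left 21582. The counts by size of ratio, the share with one sign in all cows, the brightness classes and the slopes of each cow on the others were also chosen after the data were seen. The planned filter on dim probes, well above background on at least 5 arrays on either side, removed 0 of 21595 probes, since the flag passes empty positions too. The rule named genes past the threshold with one sign in all 5 cows, filled to 8 per direction by smallest p where fewer than 5 passed, besides members of 29 gene lists and a fixed set of milk, involution and signalling genes. Because probes are not paired with genes here, the lists were not tested, and only the first 2 probes per direction are printed. The 8 on the lower side had adjusted p from 0.0484 to 0.114 and the 8 on the higher side from 0.0776 to 0.114. PPIA was matched by accession to a gene table of assembly ARS-UCD2.0 and falls outside the rule. It was chosen after its values were seen, as the only probe with a symbol.

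Replicate numbers are cow numbers, so the pairing of the sides is by animal and is contained in each ratio. Slide series was taken from the slide identifiers, all arrays being scanned on 1 day. Alternatives were background correction, median centring, Aquantile, filters, flagged features kept, single dye orientations, a replicate block with dye term, slide series, trend and robust empirical Bayes, array weights, an adjusted p of 0.10, and each cow left out.

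The fit was tested on simulated data made from the real brightness of the arrays, with 200 of 21582 probes changed. The changed probes were drawn from those above the median brightness, and the true change was the same in every cow. Feature noise was set below the SD over repeated features of the real arrays, 0.154 to 0.511. Of 50 probes each, 8% were recovered at a true log2 of 0.5, 34% at 1, 78% at 2 and 82% at 3, with 4 of 105 calls false. These shares hold for that setting and are not the power of the real comparison. The median estimates were 0.36, 0.69, 1.34 and 2.11, so the processing understated the ratios of these simulated probes. Figures were drawn with matplotlib 3.10.9.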

Results

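Gene expression was compared between the udder sides of 5 lactating Holstein cows, numbered 7849, 3049, 01, 25 and 11. In each cow one side of the udder had 1 milking per day (once daily milking, ODM) and the other had 2 (TDM) for 7 days, and both sides were biopsied on day 8. Because both sides share the circulation of one animal, a difference between them addresses the local effect of milking frequency on the gland. Each cow contributed a pair of 2-colour arrays of the same pair of RNA extracts with the dyes exchanged, 10 arrays in all. The cow is the replicate, with n of 5 unless a probe lacked values in a cow or a fit left cows out. The labels give 2 cows at 45 days in milk, 1 at 120 and 2 at 320. They also give 1 cow in lactation 1, 2 in lactation 2 and 2 in lactation 4. They do not say which cow is which, so lactation stage and lactation rank were not analysed here.

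The array carried 21595 probes besides control and empty features. Their signal was low. The median probe signal over the median empty position ran from 0.881 to 2.80 in red and from 1.15 to 2.89 in green across the 10 arrays. The share of features flagged as outliers by the scanner software ran from 1.90% to 17.7%, the highest being the array of cow 3049 with the ODM side in Cy5. The number of arrays and this signal over background limit the precision of all values below. The files name all but 9 probes by oligonucleotide IDs, those 9 by sequence accession or cluster, and give no gene symbols. Only 1 of the 21595 probes could be matched to a gene symbol, so results are given by probe, and gene groups such as milk proteins or lipid synthesis were not analysed here.

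The first question was which transcripts differed between the sides. Probe OLIGO_05822 fell on the ODM side to a log2 ratio of -2.48 ± 0.65 (SD, n = 5 cows), a signal 5.57-fold higher on the TDM side. It was lower in 5 of 5 cows, from -3.06 to -1.37, and lower on each of its arrays, from -3.10 to -1.28 (limma, adjusted p = 0.0484). Probe OLIGO_08804 fell to -1.69 ± 0.39 (SD, n = 5 cows), 3.22-fold, with cows from -2.21 to -1.12 and arrays from -2.35 to -0.80 (limma, adjusted p = 0.0484). No probe passed the threshold in the upward direction. The probe of smallest p on that side, Bt00002432, had a log2 ratio of 0.84 ± 0.11 (SD, n = 5 cows), above 0 in 5 of 5 cows (limma, adjusted p = 0.0776), and was measured with 1 dye orientation only in cow 25. Bt00007255 had 0.71 ± 0.13 (SD, n = 5 cows), also above 0 in 5 of 5 cows (limma, adjusted p = 0.113). Over 28 settings Bt00002432 ran from 0.44 to 1.30 and passed in 5, and Bt00007255 from 0.10 to 1.31 and passed in 3, among them the fit without cow 25. On single arrays these upward probes ranged from -0.26 to 1.76 and from -0.54 to 1.80.

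**Figure D1:**
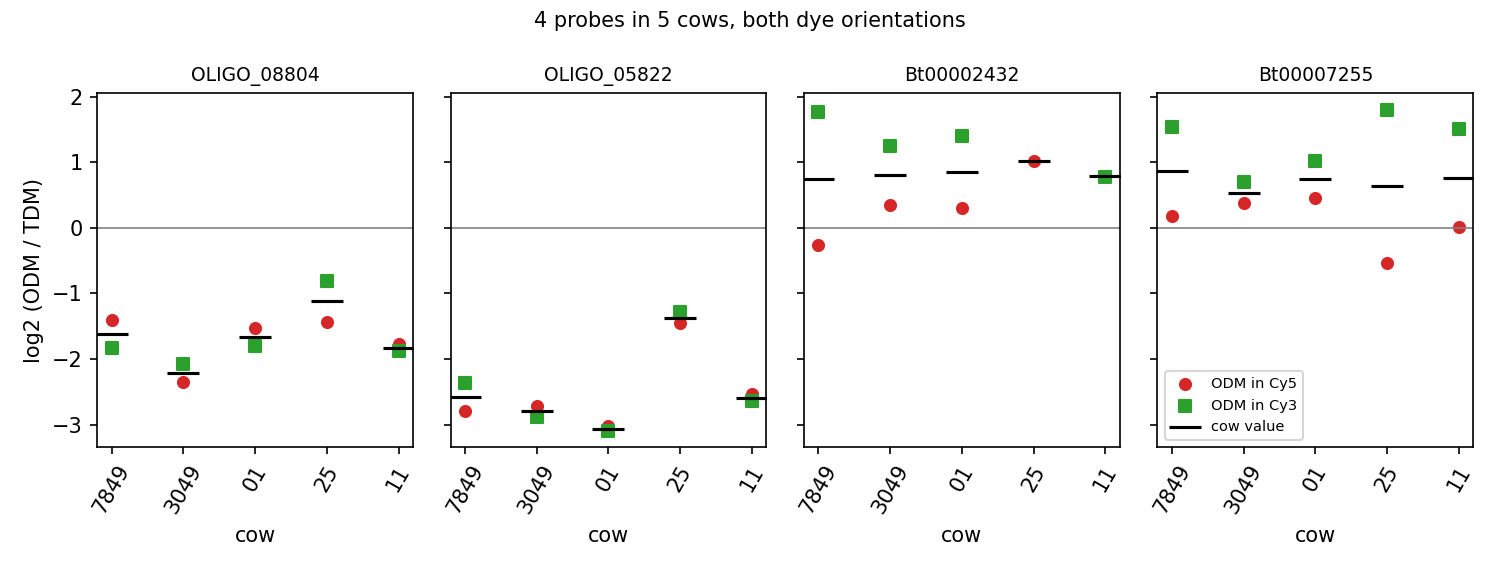
Log2 ratio of ODM over TDM signal (y axis) in each cow (x axis) for 4 probes. Circles and squares are the arrays with the ODM side in Cy5 and Cy3, and bars are the cow values. OLIGO_05822 lies between -3.10 and -1.28 on all its arrays, whereas the arrays of Bt00007255 spread from -0.54 to 1.80 between dye orientations.

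Of 21582 probes tested with limma, 2 passed a Benjamini-Hochberg adjusted p of 0.05, both lower on the ODM side. At an unadjusted p under 0.05 there were 3448 probes where 1079 would be met by chance, 1893 lower and 1555 higher. At p under 0.01 there were 1171 against 216 by chance, 688 lower and 483 higher. These chance counts are averages, and probes are not independent. With the ratios of some cows reversed in sign, a check chosen after the data were seen, the counts ran from 148 to 1867 and from 6 to 599. Both highest counts came with cow 25 alone reversed, which keeps the signs of all other cows. The remaining patterns gave at most 1480 and 225. With each array centred on its median and no loess the split at p under 0.01 turned to 331 lower and 522 higher, and without background correction it was 519 lower and 540 higher. The 10 arrays came from 2 slide series, the first with cows 7849, 3049 and 01 and the second with cows 25 and 11. With slide series as a term 0 probes passed (3060 at unadjusted p under 0.05). OLIGO_05822 was then at -2.39 and OLIGO_08804 at -1.65 (limma, adjusted p = 0.0603 and 0.0715). Within the first series 45 passed, 43 of them lower, and within the second, with 2 cows, 0 passed (1839 at unadjusted p under 0.05). The change itself differed between series for 0 probes (limma, smallest adjusted p = 0.367; 585 at unadjusted p under 0.05).

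The count of 2 rested on the replicate structure. It was 0 without cow 7849, without cow 01 and without cow 11 (2986, 2889 and 2222 probes at unadjusted p under 0.05), 2 without cow 3049, where OLIGO_08804 stayed and OLIGO_05822 was lost (limma, adjusted p = 0.0525), and 226 without cow 25, 165 of them lower. The ratios moved less than the count, from -2.76 to -2.33 for OLIGO_05822 and from -1.83 to -1.56 for OLIGO_08804 over the fits without a cow. A fit of the 10 arrays with cow as a replicate block and dye as a term gave 511 probes, 311 lower, which included both probes above. That fit gives the arrays of a cow, which share their RNA, an estimated correlation of only 0.145, so its count is not one over independent animals.

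Probes with large ratios lay mostly on the lower side. At unadjusted p under 0.01, 139 probes were lower by log2 1 or more and 20 higher, and 34 were lower by log2 2 or more and 0 higher. With median centring in place of loess the first pair became 87 lower and 148 higher, so that direction was reversed, while the second was 20 lower and 2 higher. With local background subtracted the pairs were 237 and 108, and 88 and 18. With the ODM side in Cy5 only the first pair was 263 and 52, and in Cy3 only it was 131 and 162. Leaving out a cow gave 96 to 190 lower and 8 to 48 higher by log2 1 or more, with 8 without cow 11 and 48 without cow 25, and 56 lower and 2 higher by log2 2 or more without cow 25. Within the first slide series the pairs were 170 and 25, and 57 and 0. Within the second they were 19 and 35, and 0 and 0. Of 20512 probes measured in all cows, 3326 (16.2%) had one sign in all 5, where 6.25% is met by chance, 1981 lower and 1345 higher. Among those with a ratio of log2 1 or more, 100 were lower and 17 higher. The 6.25% assumes that signs are independent between cows. Cow values from a single dye orientation keep a dye effect that cows can share.

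**Figure D2:**
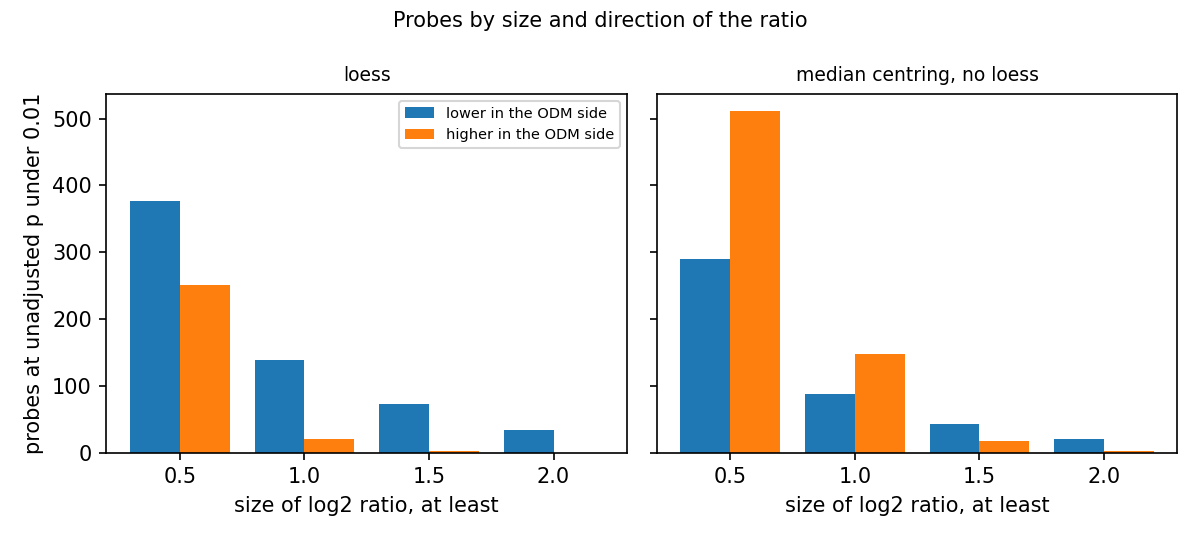
Number of probes at unadjusted p under 0.01 (y axis) by least size of the log2 ratio (x axis), lower (blue) and higher (orange) on the ODM side, after loess (left) and after median centring alone (right). At log2 1 or more the left panel has 139 lower and 20 higher, the right 87 and 148. At log2 2 or more they have 34 and 0, and 20 and 2.

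The share of probes at unadjusted p under 0.05 depended on brightness. It was 11.8% in the dimmest 10% of probes and 30.3% in the brightest 10%. The brightest 10% held 80 of the 139 probes lower by log2 1 or more and 14 of the 20 higher. After loess the median log2 ratio was -0.05 in the dimmest 10% and 0.04 in the brightest. Under median centring without loess it rose with brightness, from -0.32 to 0.43. The brightest 10% then held 61 probes lower and 284 higher at unadjusted p under 0.01.

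PPIA, the peptidyl-prolyl isomerase cyclophilin A, was the gene that could be named, through a probe printed 13 times per array. Its log2 ratio was -0.21 ± 0.26 (SD, n = 5 cows), below 0 in 4 of 5 cows, and did not pass (limma, adjusted p = 0.407). Its sign was reversed to 0.31 under median centring without loess, which left the rise with brightness. Its probe was among the brightest 10%.

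The second question was how alike the cows and dye orientations were. Across probes, which are not independent replicates, Pearson's r between the cow values of 2 cows averaged 0.257 and ran from 0.0622 to 0.578. Between the 2 arrays of one cow r averaged 0.0729, from -0.216 in cow 25 to 0.366 in cow 7849. A dye effect passed the adjusted threshold for 4972 of 21448 probes. With the probe dye effect of the other cows removed, r between the arrays of a cow ran from 0.107 in cow 25 to 0.310 in cow 11. In the brightest 20% of probes the averages were 0.367 between cows and 0.326 between the arrays of a cow, where removing the dye effect gave 0.151 in cow 25 and 0.471 to 0.637 in the others. Each cow's ratios in those probes were set against the mean of the other 4. The slope was 0.923 in cow 7849, 0.887 in cow 3049, 0.761 in cow 01, 1.02 in cow 11 and 0.130 in cow 25. The low ratios of cow 25 raise the slopes of the others, which ran from 0.603 to 0.790 when it was left out of the mean. Cows 25 and 11 were on slides of the same series.

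**Figure D3:**
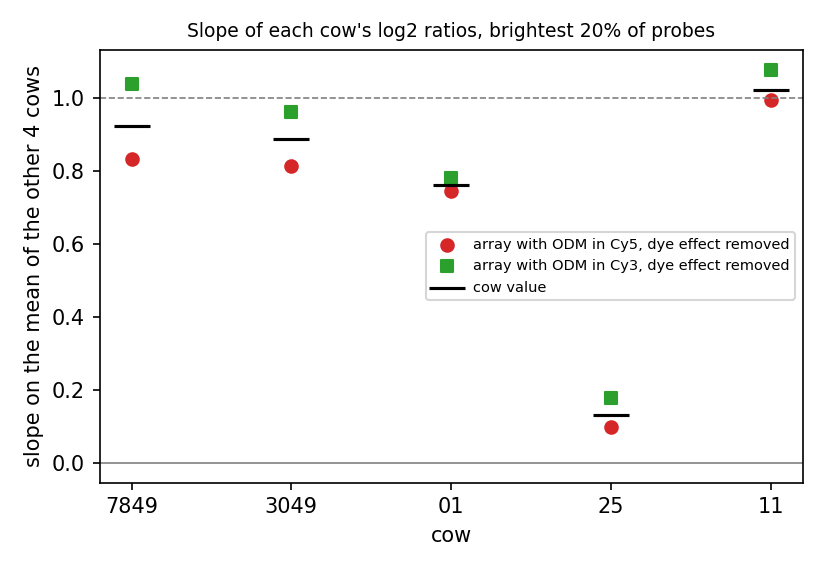
Slope of each cow's log2 ratios on the mean of the other 4 cows (y axis) by cow (x axis), over the brightest 20% of probes. Bars are cow values, and circles and squares the arrays with the ODM side in Cy5 and Cy3 after the probe dye effect of the other cows was removed. Cow 25 lies at 0.130 and the others between 0.761 and 1.02.

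The third question was whether one udder side gave more detected features. By the scanner's flag the mean was 21684.8 ± 19.1 features on the ODM and 21688.1 ± 25.6 on the TDM side (SD, n = 5 cows), a difference of -3.3 (exact sign-flip permutation test, two-sided, p = 0.563, where 5 cows allow no p under 0.0625). The flag also passed 98.6% or more of the empty positions on each array and so does not separate signal from background. Counting features above 2 times the median background gave 7958.2 ± 2510 and 6498.7 ± 2708, a difference of 1459.5 (exact p = 0.438), in the opposite direction. Counting features above the 95th percentile of the empty positions, a definition chosen after the data were seen, gave 10387 ± 3361 and 11202.3 ± 2870, a difference of -815.3 (exact p = 0.813). None of these differences exceeded the spread between cows.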

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

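The tests of reversed dye labels, noise and background compression in this part, and the values with cow 25 or saturated probes left out, were chosen after cow 25 was seen to stand apart. Of 15 sets of values tested for a cow or array far from the others, 4 met the criterion, where chance gives about 1 in 20. The array of cow 3049 with the ODM side in Cy5 had 17.7% of its features flagged by the scanner software, far above the other arrays of that orientation. The other 3 are values of cow 25.

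Cow 25 stood apart in OLIGO_05822, at a log2 ratio of -1.37, in the share of the other cows' changes it kept, and in the SD of log2 ratios of its array with the ODM side in Cy3, 0.358 and the lowest of that orientation. For 227 probes with log2 1 or more at unadjusted p under 0.01 in the other 4 cows, the median ratio of cow 25 in the same direction was 9.79% of theirs, with 65.2% of probes on the same side. The other cows, each over its own 102 to 126 probes, kept 97.8% to 133%, but cow 25 lowers the values they are set against. With cow 25 left out of these they kept 70.6% to 114% over 195 to 271 probes.

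The lower slope of the 2 arrays of cow 25 on the other cows, dye effect removed, was 0.0979, above 0, which argues against an array with reversed dye labels or exchanged sides. The arrays of cow 25 were not noisier by the SD over repeated features, 0.266, where the other cows ran from 0.267 to 0.378. Over the 6 repeated probes without saturated features the SD was 0.250 against 0.280 to 0.384. Noise in its own ratios adds scatter and would not by itself lower its slope on the other cows, so the SD does not bear on that slope. Compression by background is argued against by the slope with local background subtracted, which stayed at 0.162. Extracts from the same side would give ratios near 0. The arrays of cow 25 instead had -1.46 and -1.28 for OLIGO_05822 and -1.43 and -0.80 for OLIGO_08804. These 2 probes had the smallest p in a fit that included cow 25. They also passed in the fit without cow 25 (limma, adjusted p = 0.00106 and 0.00296). As 2 probes picked from many by their p, they do not decide whether its extracts came from the same side. Same-side or partly mixed extracts, compression by signal of the kind at empty positions, and a cow that responded little stay open. No biological explanation was tested, since the labels do not tie lactation stage, lactation rank or gestation to a cow.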

How the results depend on the processing

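The values under median pixel intensity, both dyes only, without the Cy5 array of cow 3049, dye effect subtracted, probes above empty positions, features with a value in the deposited table, at least 2 cows per probe and single arrays left out were chosen after the data were seen. Against 2 probes at adjusted p 0.05, 0 passed with local background subtracted, median centring, flagged features kept, slide series as a term, the second series alone, array weights or median pixel intensity (limma, 1772 to 3614 at unadjusted p under 0.05). The count was 45 in the first series, 5 with trend and robust fitting, 6 with both dyes only, 6 without the Cy5 array of cow 3049, 10 with the dye effect subtracted and 4 at adjusted p 0.10. It was 984 and 478 with ODM in Cy5 or Cy3 only, and 511 with the replicate block and dye term. Leaving out a cow gave 0 to 226, and leaving out 1 of the 10 arrays 0 to 26. Apart from fewer cows or probes, and dye bias in the single orientations, the cause was not tested. Against 3448 probes at unadjusted p under 0.05, 16.0% of those tested, there were 6837 with Cy5 only, 1799 and 1839 within the series, and 2222 to 3373 without a cow. With local background subtracted there were 1772 of 16967 tested (10.4%). Among probes above empty positions there were 2225 of 12765 (17.4%), a higher share than in the main fit. The detected-feature difference was 1459.5 at 2 times background and -7.5 to 0.125 without a cow. PPIA was reversed to 0.31 under median centring. Over 28 settings OLIGO_05822 ran from -3.07 to -1.98 and was lost in 11, OLIGO_08804 from -2.18 to -1.34 and in 10. Aquantile and the planned filter moved nothing and test nothing. The mean r between cows moved by less than its spread. Low signal over empty positions limits dim probes. Gene lists, deposited-table ratios and several probes of a gene were not run.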

Other observations

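The tests of array noise, scaling, dim probes, dye bias and sign patterns in this part were chosen after the result was seen. Besides PPIA, 8 probes were printed 13 times on each array. Of these, 3 had saturated features, so that their ratios are not given. The log2 ratios of the other 5 ran from -0.15 to 0.45 and none passed (limma, smallest adjusted p = 0.217). Only 50 probes were called in both single-orientation fits, 49 of them in the same direction, where independent lists would share 22.2.

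The excess of probes lower by log2 1 or more was weighed against 3 technical explanations. Dye orientation and slide series were not among them and stay open. The ratio of lower to higher probes was 5.06 with the ODM side in Cy5 only and 0.809 in Cy3 only. It was 6.8 in the first slide series alone and 0.543 in the second. A single noisy array is argued against by the ratio of lower to higher probes without each of the 10 arrays in turn, at lowest 4.37. Noise of dim probes is argued against by a ratio of 5.71 in the brightest 10% of probes. The scaling may account for it, since the ratio was 0.588 under median centring, though 7.5 without background correction, 2.19 with local background subtracted, and 3.51 with the scanner software's ratios. Median centring left a rise of the log2 ratio with brightness that loess removed, so the value of 0.588 includes that trend. For log2 2 or more the scaling is argued against, with a lowest ratio of 4.89 under 4 scalings, with local background subtracted.

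The larger counts of the single-orientation fits may come from dye bias. Probes called with the ODM side in Cy5 had a median ratio of 0.79 there and -0.09 in the same direction on the Cy3 arrays, -0.114 of it, and 59.4% were opposite. A balanced swap cancels this bias only where a probe has values in both dye orientations of a cow. The main fit also kept cow values from a single orientation, so the bias is not fully removed there. With both dyes only, 6 probes passed, against 2 in the main fit. The counts of 984 and 478 come from fits without a swap and may hold dye effects. No biological explanation was tested.

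The 5 cows allow 16 sign patterns, too few for a share under 0.05. The real pattern gave 2 probes past the threshold, and 1 of the 16 patterns, the real one, gave as many. The highest other gave 0 (1867 at most at unadjusted p under 0.05).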
